A study of Mus musculus with 4 samples.

How the data were processed

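RNA was measured in 4 mouse samples: 2 labelled as wild-type (WT) cervical lymph nodes and 2 samples from mice lacking Becn1 in myeloid cells (labelled Becn1-M-KO, here KO). All mice were C57BL/6 at postnatal week 20, per the labels. The series describes the KO samples as B cell lymphomas and the WT samples as node controls, so genotype and tumour cannot be told apart. Total RNA was depleted of ribosomal RNA and sequenced on an Ion Torrent instrument, per the labels' protocols. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

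The authors deposited read counts per gene as whole numbers, not normalized, per the file headers. The build mm10 and DESeq2 1.62 are named in the submitters' processing notes, without a role; the aligner and the counting tool are not given in the sources used here. The length listed for each of the 38087 genes equals its whole genomic span, so intronic reads may be counted. Ccl2 and the gene Gm17268 on the opposite strand had a reads ratio of 1.002, so overlapping genes may share reads. The authors deposited a second table of log2 values, in which the median over the 4 libraries is 0 for each of the 38087 genes (within 1e-05). The authors' deposited table of comparisons gives a log2 fold change and an unadjusted p-value per gene, per the file headers. The other 8 columns of per-sample values (average coverage and low-coverage bases) were not used here.

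Depth was 16141605 and 17874699 reads in WT replicates 1 and 2, and 15604247 and 20067004 reads in KO replicates 1 and 2. A count of 0 allows up to 3 reads, or 0.149 to 0.192 CPM of the library total. Intervals are at the 95% level. Intervals and floors cover counting error only, except the bootstrap intervals over list members, which cover spread between genes.

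Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM scaling, filterByExpr with a minimum count of 10 and a total of 15). Adjusted p-values are Benjamini-Hochberg values from this test unless another is named, with a threshold of 0.05. Standard errors (SE) are the fold change divided by the root of the F statistic. Levels are counts scaled to library size (CPM) with TMM factors unless said to be of the library total. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 30 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries, so it may miss real shifts. Of 437 list entries, 432 matched a gene.

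The 30 lists covered B lineage cells (pan-B, mature follicular, precursor, germinal centre, plasma cell, immunoglobulin constant regions), T cells, NK and cytotoxic lymphocytes, and immune checkpoint and regulatory T cells. They also covered neutrophils, monocytes and macrophages, dendritic cells, fibroblasts and reticular stroma, endothelium and high endothelial venules, erythroid cells, salivary and other epithelium, skeletal muscle and adipocytes. The other lists were mitosis, DNA replication, MYC and ribosome biogenesis, glycolysis and hypoxia, autophagy core, interferon response, inflammatory cytokines and chemokines, NF-kB targets, p38 MAPK pathway, BCL2 family, MHC class II, and immediate early and stress genes. The lists, the main tests, the naming rule and all alternatives except the crossed pairing were fixed before the data were examined.

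Named genes were Becn1; the 10 largest rises and 10 largest falls past the threshold with an average log2 CPM of at least 3 and no overlap between groups; up to 3 members per list with the smallest p; and Cd274, Il10, Il21, Cxcl9, Mapk14, Cd5, Myc and Bcl2. Unnamed predicted genes, immunoglobulin and T cell receptor segments, pseudogenes and small RNAs were left out of the largest changes. Genes named outside this rule were chosen after their values were seen. They are the secretory gland and sex-linked genes, Epcam, Il1a, Cxcl1, Il27, Pax5, Ebf1, Derl3, Xbp1, Txndc5 and further immunoglobulin genes. The 6 macrophage genes lower against WT replicate 2, Alas2 and E230016K23Rik are also among them. Not every gene that the rule names is reported here.

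Alternatives were DESeq2 size factors, library totals alone, no count filter, a stricter filter (1 CPM in 2 libraries and 20 reads in all), DESeq2 1.42.0, limma-voom, a replicate block, each library left out, gene classes left out, and a test against a log2 fold change of 1. With 1 library left out, its group has 1 sample, so p-values and calls there say nothing of the spread within that group. Both steps were tested on simulated counts with 200 changed genes. At the spread of the 4 libraries, on 20323 simulated genes, 0 of 67 genes changed 2-fold, 12 of 67 changed 4-fold and 65 of 66 changed 16-fold were recovered, with 3 false calls. For KO against WT replicate 2, on 21239 genes, 54 of 67, 67 of 67 and 66 of 66 were recovered, with 10 false calls. Both simulations gave WT and KO the same spread. In the data the WT pair varied far more than the KO pair (Pearson chi-square per degree of freedom 766.9 against 12.06). The simulations therefore do not give the rate of recovery or of false calls in these data.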

Results

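Gene expression was compared between 2 samples labelled WT cervical lymph node and 2 cervical samples of mice with a myeloid deletion of Becn1. The comparison asks how the transcriptome of the lymphomas of these mice differs from the samples labelled WT nodes. The first WT library held few lymphocyte reads, so the tissue it represents is in doubt. Of 38087 genes, 30898 had at least 1 read and 20695 were tested. Totals ranged from 15604247 to 20067004 reads per library.

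Becn1, which encodes the autophagy protein Beclin-1, lies on chromosome 11 from 101285952 to 101302286. Its level was 54.8 and 63.4 CPM in WT and 49.5 and 53.3 CPM in KO. The log2 fold change was −0.20 (SE 0.21, adjusted p = 0.557), so no difference was shown. Against WT replicate 2 alone, which leaves 1 WT library, it was −0.30. Over the alternatives run for this gene with all 4 libraries, the adjusted p ranged from 0.526 (limma-voom) to 0.849 (DESeq2). With library totals alone the sign turned (0.36). The deletion was in myeloid cells only, reads were counted over the whole gene, and Cntd1 overlaps on the other strand, so the whole-tissue level does not check the genotype.

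The WT libraries held abundant salivary gland transcripts. Spt1, a salivary secretory protein gene, took 32.0% of the reads of WT replicate 1, followed by Scgb1b27 at 5.11%, Scgb2b27 at 4.32% and Car6 at 4.19%. In WT replicate 2 the leading genes were Dcpp2 at 5.76%, BC048546 at 4.72% and Dcpp3 at 3.05%. The KO libraries were led by the immunoglobulin gene Ighg2c, at 1.51% and 1.45%. Summed reads of the T cell list were 24.8 CPM of the library total in WT replicate 1, 1763 in WT replicate 2, and 1340 and 1328 in KO. The WT libraries correlated at 0.857 (log2 CPM, across genes, which are not independent), the KO libraries at 0.988, WT replicate 1 with KO at 0.628 and 0.649, and WT replicate 2 with KO at 0.831 and 0.846. The first principal component held 85.2% of the variance.

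**Figure D1:**
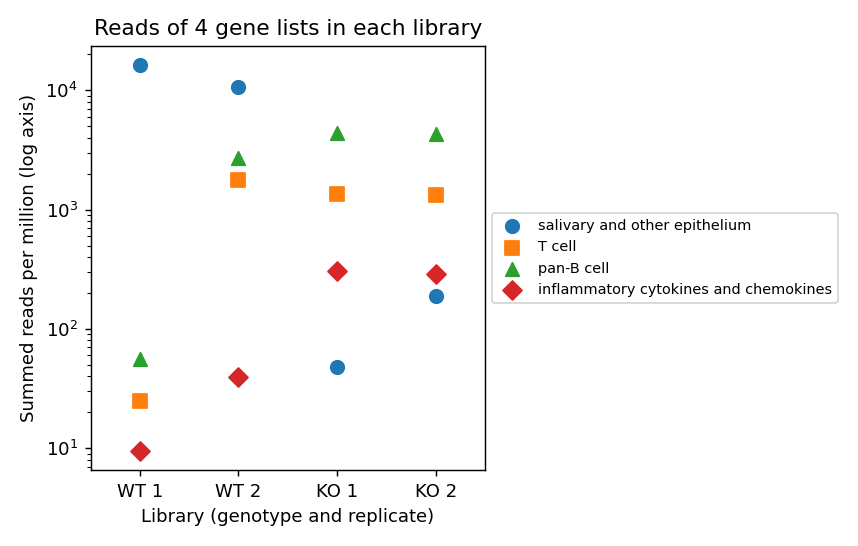
Summed CPM of the library total (log axis) of 4 gene lists in each of the 4 libraries, 1 point per list and library. T cell list reads stand at 24.8 in WT replicate 1 against 1763 in WT replicate 2, and epithelial list reads are highest in the WT libraries.

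Sex-linked genes also separated the groups. Xist, expressed from the inactive X chromosome of females, had 2088 and 5314 reads in WT and 3 and 34 in KO (adjusted p = 0.0547). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty rose, by log2 fold changes of 4.46, 7.41, 5.92 and 2.73. Eif2s3y had 1 and 6 reads in WT and 767 and 1083 in KO (SE 0.41, adjusted p = 0.037). Sex therefore went with genotype in these libraries.

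Across the transcriptome, 216 genes rose and 451 fell in KO, with F10, Ptgs2, Gpnmb and the Y-linked Eif2s3y among the 10 largest named rises. F10, coagulation factor X, rose from 0.242 and 0.334 CPM to 90.1 and 84.0 CPM (log2 fold change 8.14, SE 0.31, adjusted p = 0.037). Ptgs2, the inducible cyclooxygenase, rose by 7.80 (SE 0.45), Gpnmb by 7.76 (SE 0.72) and Nos2, the inducible nitric oxide synthase, by 7.38 (SE 0.60). Saa3, Clec4e, Irg1, Fpr2 and Clec4d rose by 7.30, 6.97, 6.93, 6.27 and 6.06; Fpr2 overlaps Fpr3. Of the rises, 36 were immunoglobulin or T cell receptor genes. All 667 calls had adjusted p-values between 0.037 and 0.05, and 5571 genes had an unadjusted p under 0.05. Leaving out WT replicate 1 gave 4573 rises and 4988 falls, with all 216 and 451 calls kept; leaving out WT replicate 2 gave 6887 and 6922. Leaving out either KO library, using library totals alone or adding a replicate block gave 0 calls each with edgeR, and DESeq2 on all libraries gave 1277 and 2382. At those 0 counts the genes at an unadjusted p under 0.05 numbered 732 and 1318 (higher and lower) without KO replicate 1, 743 and 1342 without KO replicate 2, 1472 and 1505 with library totals, and 1866 and 2734 with the block.

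**Figure D2:**
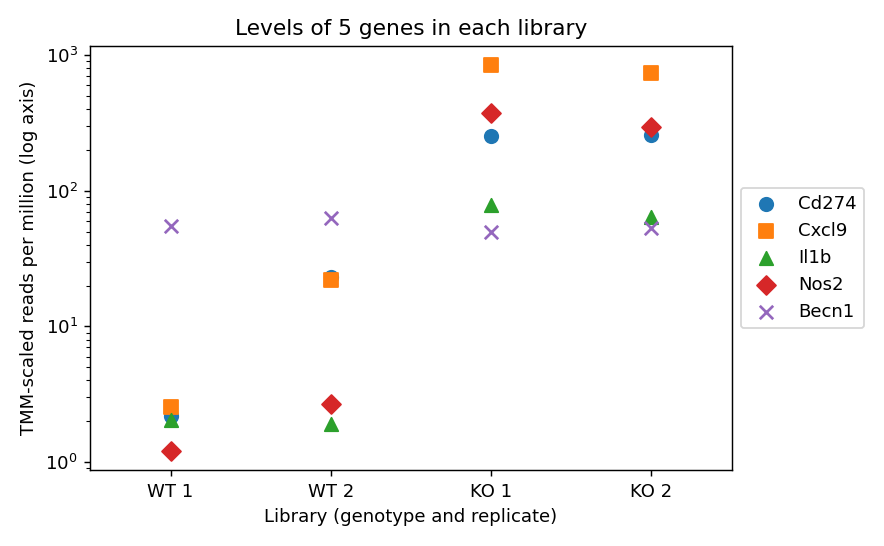
TMM-scaled CPM (log axis) of Cd274, Cxcl9, Il1b, Nos2 and Becn1 in each of the 4 libraries, 1 point per gene and library. Nos2 stands at 1.21 and 2.67 in WT and at 372 and 294 in KO, while Becn1 lies between 49.5 and 63.4 in all 4.

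Azgp1, Gpx2, Lman1l and Slc10a5 were among the 10 largest named falls, which include 1 member of the epithelial list, Krt18. Azgp1, a secreted glycoprotein gene, had 246 and 1227 reads in WT and 0 in both KO libraries, at least 770-fold lower against a floor of 3 counts over the group (adjusted p = 0.0459). Gpx2, which overlaps Fntb, had 1 read in KO against 761 in WT, a ratio of 1190 (95% counting interval 213 to 47200). Slc10a5, Bglap2 and Six2 had 1, 3 and 3 KO reads, with ratios of 884 (158 to 35000), 552 (188 to 2680) and 442 (151 to 2150). Lman1l, Kcne1, B3gnt6, Foxa1 and Krt18 fell, with log2 fold changes of −9.65, −9.15, −9.11, −9.05 and −8.92. The salivary and other epithelium list fell (median −8.37 over 13 genes, adjusted p = 2.3e-07; adjusted p = 0.604 with an estimated correlation). Krt18, Krt14, Epcam and Cdh1 fell, 4 of 13 over all genes and 12 adjusted over the list alone. Epithelial list reads were 16230 and 10680 CPM of the library total in WT and 47.7 and 188 in KO.

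Inflammatory cytokines and chemokines rose as a list, with a median of 3.06 over 17 genes (adjusted p = 1.7e-09; adjusted p = 0.588 with an estimated correlation). Il1b rose from 2.05 and 1.91 CPM to 77.9 and 63.6 CPM (5.16, SE 0.26, adjusted p = 0.037), Ifng by 5.06 (SE 0.53) and Ccl2 by 4.58 (SE 0.24). Ccl2 overlaps Gm17268 on the opposite strand (reads ratio 1.002), so its reads may not be its own. Il1a, Cxcl1 and Il27 rose by 2.41, 3.46 and 3.28, making 6 of 17 over all genes and 14 adjusted over the list alone. The interferon response list rose with a median of 1.48 over 20 genes (adjusted p = 4.2e-05; adjusted p = 0.588 with an estimated correlation). Its members Iigp1, Gbp2 and Cxcl10 rose by 4.75, 4.59 and 4.46 (SE 0.58 each), 3 of 20 over all genes and 9 adjusted over the list alone. The list median was 1.54 without WT replicate 1 and 2.74 without WT replicate 2. Cxcl10 overlaps Art3 on the opposite strand (reads ratio 1.311), so its reads may not be its own. Both lists were also called by fry (adjusted p = 0.0135). In WT replicate 1, where T cell list reads were lowest, inflammatory list reads were 9.48 CPM of the library total, against 39.6 in WT replicate 2 and 305 and 290 in KO.

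Myeloid lists rose as well. The monocyte and macrophage list had a median of 1.49 over 18 genes (adjusted p = 0.00070; adjusted p = 0.604 with an estimated correlation). Fcgr1, the high-affinity IgG receptor gene, rose by 2.0 (SE 0.27), while C1qb had a value of 2.47 (adjusted p = 0.0547); 2 passed over all genes and 11 higher and 1 lower adjusted over the list alone. By sign 12 of the 18 values were positive and 6 negative, and against WT replicate 2 12 members rose and 6 fell over all genes, among them Marco (−2.84), Siglec1 (−2.81), Cd163 (−2.23), Timd4 (−2.05), Lyz2 (−2.03) and Mrc1 (−1.65). The neutrophil list rose with a median of 1.78 over 12 genes (adjusted p = 0.0023; adjusted p = 0.604 with an estimated correlation). Lcn2 rose by 4.85 (SE 0.35), the only one of 12 over all genes, with 4 higher and 1 lower adjusted over the list alone; Ltf had a value of −2.99 (adjusted p = 0.0560) and Il1r2 of 2.15. The dendritic cell list was not called (median 0.84, adjusted p = 0.180; median −0.014 without WT replicate 1), though Itgax, which encodes CD11c, rose by 4.08 (SE 0.51); 1 of 11 passed over all genes and 1 adjusted over the list alone. The MHC class II list rose by camera with the preset correlation, with a median of 2.37 over 10 genes (adjusted p = 0.0023, and 0.632 with an estimated correlation). It had 0 members passing either way and was not called by fry (adjusted p = 0.265). Its median was 1.53 without WT replicate 1 and 4.55 without WT replicate 2. NF-kB targets rose with a median of 1.35 over 12 genes (adjusted p = 0.0019; adjusted p = 0.632 with an estimated correlation), also with 0 members passing over all genes or adjusted over the list alone. The NF-kB median was 0.68 without WT replicate 1 and 2.83 without WT replicate 2. The monocyte and macrophage and neutrophil medians were 1.60 and 1.52 without WT replicate 1, and 2.41 and 3.01 without WT replicate 2. The dendritic cell median was 3.43 without WT replicate 2.

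Lists of B lineage genes were mostly higher in KO, in comparison with a WT group whose first replicate held 56.2 CPM of pan-B list reads (of the library total) against 2719 in the second. The pan-B cell list rose with a median of 1.40 over 15 genes (adjusted p = 0.0076; adjusted p = 0.690 with an estimated correlation); Fcrla, Blnk and Cd72 had values of 1.49, 1.45 and 1.40. Without WT replicate 1 these 3 genes rose by 0.89, 0.81 and 0.77, and without WT replicate 2 by 2.57, 2.65 and 2.55. Pax5 (−0.84) and Ebf1 (−0.92) were the only pan-B members with negative values without WT replicate 1. The pan-B median was 0.77 without WT replicate 1 and 7.30 without WT replicate 2. The mature follicular list rose with a median of 1.19 over 13 genes (adjusted p = 0.0375; adjusted p = 0.722 with an estimated correlation), and without WT replicate 1 its median was 0.22 (adjusted p = 0.362), against 6.8 without WT replicate 2. The germinal centre list rose with a median of 1.28 over 10 genes (adjusted p = 0.0107; adjusted p = 0.604 with an estimated correlation). In these 3 lists 0 members passed over all genes or adjusted over the list alone. The germinal centre and immunoglobulin constant medians were 0.87 and 2.78 without WT replicate 1, and 2.06 and 8.61 without WT replicate 2. The immunoglobulin constant list rose with a median of 3.74 over 9 genes (adjusted p = 0.00089; adjusted p = 0.604 with an estimated correlation), with 0 members passing either way. Ighg2c stood at 29.1 and 178 CPM in WT and 11829 and 11186 CPM in KO (6.79, SE 1.52, adjusted p = 0.0933). The plasma cell list was not called by camera (median 1.5, adjusted p = 0.0613) but was by fry (adjusted p = 0.0135), and by camera without WT replicate 1 (adjusted p = 0.0040; adjusted p = 0.545 with an estimated correlation), KO replicate 1 (adjusted p = 0.0276; adjusted p = 0.772 with an estimated correlation) or KO replicate 2 (adjusted p = 0.0211; adjusted p = 0.706 with an estimated correlation). Sdc1, which encodes CD138, rose by 1.61 (SE 0.19), 1 of 12 over all genes, with 4 higher and 1 lower adjusted over the list alone. The 4 plasma cell members with negative values, among them Fkbp11 (89.5 and 46.0 CPM in WT), were all highest in WT replicate 1 after TMM scaling (factor 0.513 there). By CPM of the library total only Derl3 was highest there (117, against 22.3 in WT replicate 2). Fkbp11 stood at 45.9 and 53.9 in WT by that measure, and Xbp1 (320) and Txndc5 (277) were lowest in WT replicate 1. Pan-B list reads were few in WT replicate 1, so the levels of these genes there may not come from plasma cells. The precursor B cell list was not called (median −0.21, adjusted p = 0.622), but was called lower without WT replicate 1 (−0.93, adjusted p = 0.0092; adjusted p = 0.545 with an estimated correlation), and its median was 1.98 without WT replicate 2. Its member Cd24a fell by 2.63 (SE 0.31, adjusted p = 0.0475), 1 of 13 over all genes and 2 lower adjusted over the list alone. Cd24a stood at 528 CPM in WT replicate 1, where pan-B list reads were few, so its fall may not come from B cells.

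The T cell list was called higher with both WT libraries and lower without WT replicate 1. Its median was 0.42 over 21 genes (adjusted p = 0.0344; adjusted p = 0.726 with an estimated correlation), and −0.55 against WT replicate 2 (adjusted p = 0.00079; adjusted p = 0.545 with an estimated correlation). Without WT replicate 2 it was 5.73. In the test of all libraries 0 members passed over all genes or adjusted over the list alone; Cd28, Cd6 and Zap70 had values of 0.95, 1.0 and 0.84, but 0.0455, 0.039 and −0.0995 without WT replicate 1 and 4.69, 6.01 and 4.98 without WT replicate 2. The NK and cytotoxic list rose with a median of 1.11 over 14 genes (adjusted p = 0.0023; adjusted p = 0.604 with an estimated correlation); the median was 0.39 without WT replicate 1 and 2.88 without WT replicate 2. Gzmk rose by 3.26 (SE 0.27), 1 of 14 over all genes and 3 adjusted over the list alone; Tbx21 and Gzmb had values of 3.41 and 2.07. The immune checkpoint and regulatory T cell list rose with a median of 1.54 over 16 genes (adjusted p = 0.00025; adjusted p = 0.604 with an estimated correlation), with 0 members passing over all genes and 1 adjusted over the list alone; its median was 0.92 without WT replicate 1 and 2.99 without WT replicate 2.

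Cd274, which encodes the checkpoint ligand PD-L1, stood at 2.17 and 23.0 CPM in WT and 255 and 255 CPM in KO. Its log2 fold change of 4.32 (SE 1.24) missed the threshold (adjusted p = 0.133). It was 3.47 without WT replicate 1 and 6.85 without WT replicate 2, each with 1 WT library left. Cxcl9, an interferon-induced chemokine gene, had a value of 5.98 (SE 1.28, adjusted p = 0.0873). It was 5.16 without WT replicate 1 and 8.26 without WT replicate 2. Il21 had a value of 3.35 (adjusted p = 0.0726), Il10 of 0.79 (adjusted p = 0.283), Myc of 0.68 (adjusted p = 0.125) and Mapk14, which encodes p38 alpha, of −0.33 (adjusted p = 0.425). The Il10 value was 0.47 without KO replicate 1 and 1.08 without KO replicate 2. Cd5 and Bcl2 had values of 0.58 and 0.24, which turned to −0.39 and −0.60 without WT replicate 1.

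Proliferation lists rose. The mitosis list had a median of 2.10 with all 17 members positive (adjusted p = 1.9e-06; adjusted p = 0.604 with an estimated correlation), 0 passing over all genes and 7 adjusted over the list alone. Foxm1, Bub1b and Bub1 had values of 2.31, 2.24 and 1.83. The DNA replication list had a median of 1.01 with all 19 members positive (adjusted p = 3.1e-05; adjusted p = 0.604 with an estimated correlation), 0 passing either way; Rrm2 had a value of 2.51. Both lists were also called against WT replicate 2, with medians of 1.52 and 0.74 (adjusted p = 0.545 with an estimated correlation for each).

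Among stromal and other tissue lists, the erythroid list fell with a median of −3.64 over 5 genes (adjusted p = 0.0019; adjusted p = 0.604 with an estimated correlation); 0 members passed over all genes and 5 adjusted over the list alone, and all 5 had negative values. Leaving out haemoglobin, mitochondrial and rRNA genes left 1 tested member, Alas2 (−2.95, adjusted p = 0.185 as a list). The fibroblast and reticular stroma list rose with a median of 1.27 over 13 genes (adjusted p = 0.0390; adjusted p = 0.604 with an estimated correlation). Its member Acta2, smooth muscle actin, fell by 3.59 (SE 0.41), 1 of 13 over all genes, with 2 higher and 2 lower adjusted over the list alone; the list call was lost without KO replicate 1 (adjusted p = 0.0727). The endothelium list (median −0.46, adjusted p = 0.967), the skeletal muscle list (median 0.63, adjusted p = 0.268) and the adipocyte list (median −1.01 over 2 tested genes, adjusted p = 0.274) were not called, with 0 members passing over all genes; adjusted over the list alone, 1 adipocyte member passed, lower. The skeletal muscle median was −0.025 without WT replicate 1 and 1.72 without WT replicate 2. Without WT replicate 1 the endothelium list was called lower (−0.61, adjusted p = 0.0139; adjusted p = 0.636 with an estimated correlation), and its median was 2.05 without WT replicate 2. The adipocyte list, then with 7 tested genes, was called lower without WT replicate 1 (−4.71, adjusted p = 0.0018; adjusted p = 0.545 with an estimated correlation) and without KO replicate 1 or 2 (adjusted p = 0.0102 and 0.0218; adjusted p = 0.772 and 0.706 with an estimated correlation). Glycam1, a marker of high endothelial venules, had 0 and 10847 reads in WT and 139 and 98 in KO (adjusted p = 0.329).

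With all 4 libraries, lists of autophagy and survival pathways were not called, and 0 of their members passed over all genes. The autophagy core list had a median of −0.29 over 25 genes (adjusted p = 0.158; called lower without WT replicate 2, −0.39, adjusted p = 0.0308, and adjusted p = 0.499 with an estimated correlation) and the p38 MAPK list −0.12 over 12 (adjusted p = 0.905). The BCL2 family list had a median of 0.39 over 13 genes (adjusted p = 0.485), with 2 higher and 2 lower adjusted over the list alone; its median was 0.19 without WT replicate 1 and 1.34 without WT replicate 2. MYC and ribosome biogenesis had a median of 0.19 (adjusted p = 0.184), glycolysis and hypoxia 0.37 (adjusted p = 0.279; 4 higher and 2 lower adjusted over the list alone), and immediate early and stress genes 0.54 with a mean of −0.03 (adjusted p = 0.296). Without WT replicate 1 the autophagy and immediate early medians were −0.16 and 0.35, and without WT replicate 2 the MYC and glycolysis medians were 0.34 and 0.21.

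**Figure D3:**
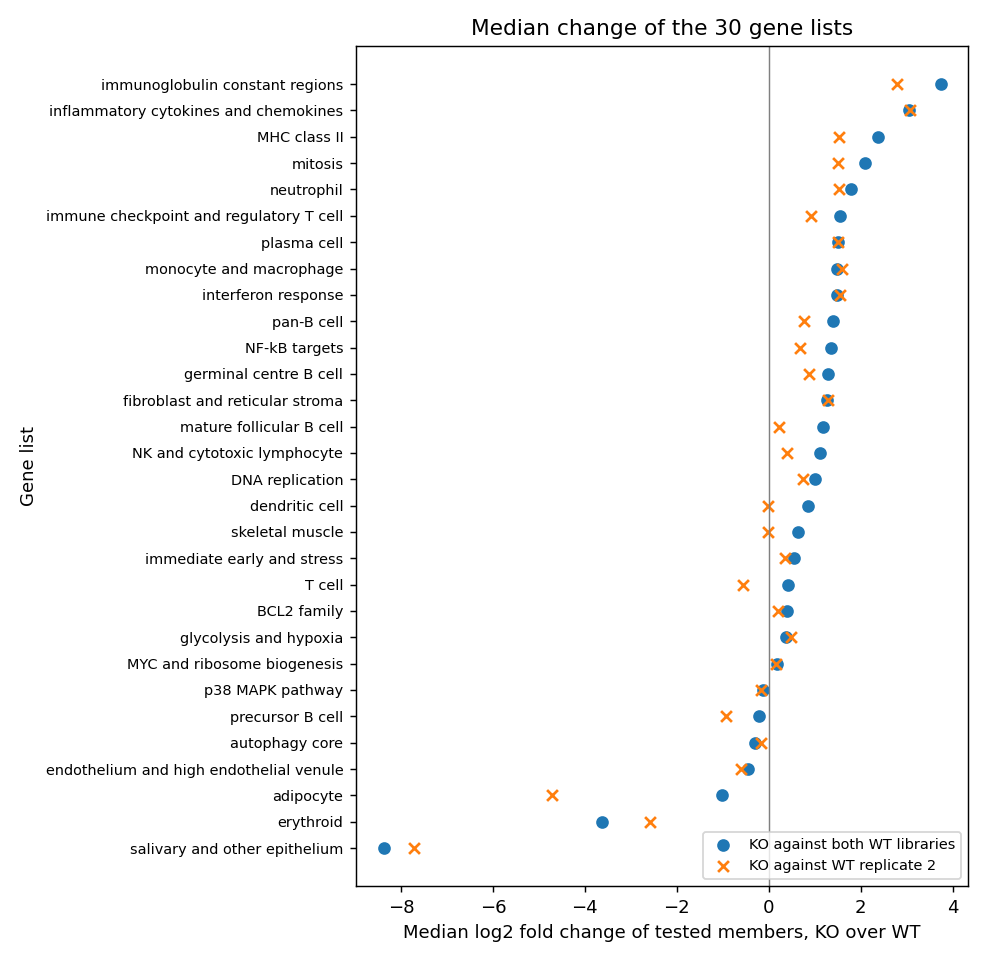
Median log2 fold change (KO over WT, x axis) of the tested members of each of the 30 gene lists (y axis), with circles for all 4 libraries and crosses for KO against WT replicate 2. The T cell list lies at 0.42 with both WT libraries and at −0.55 against WT replicate 2, and the inflammatory list at 3.06 and 3.07.

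The authors' deposited table lists 5511 genes, 2482 higher and 3029 lower in KO. Of the 667 edgeR calls, 632 were in the authors' deposited table and 631 had the same direction there. The exception was E230016K23Rik, with 84 and 348 reads in WT and 1466 and 1949 in KO, but −5.59 in the authors' deposited table. The authors' deposited short lists hold 86 higher and 71 lower genes, of which edgeR tested 112 and called 42, all 112 in the same direction. F10 had a log2 fold change of 8.56 and Azgp1 of −9.32 in the authors' deposited table. Group differences in the log2 values that the authors deposited for each gene, which equal the fold changes of the authors' deposited table, correlated with the edgeR fold changes at a Spearman rho of 0.911 across 20695 genes, which are not independent, and both sets rest on the same libraries.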

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

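The crossed pairing was chosen after seeing the data; the other alternatives were planned. Becn1 was not called in the alternatives run for it with all 4 libraries. The test against a log2 fold change of 1 and the crossed block were not run for it. Without each library in turn its log2 fold change ranged from −0.30 to −0.11, and with library totals alone it was 0.36. The 216 higher and 451 lower calls became 0 and 0 with library totals alone, a scaling that moved the median of all genes to 0.60. They became 542 and 1188 without a count filter, 1277 and 2382 with DESeq2 (8387 genes with no adjusted p), and 16 and 24 against a log2 fold change of 1. The cause was not tested. Without each library in turn they ranged from 0 to 6887 and from 0 to 6922. Across genes, the deviations of replicate 1 from its group mean correlated at −0.108 between WT and KO. That value cannot tell whether the replicate numbers mark a shared batch or pairing. The replicate block gave 0 and 0 calls. The crossed block gave 202 and 643. The 16 higher and 2 lower lists became 0 and 0 with an estimated correlation and 3 and 0 with fry, and ranged from 15 to 17 and from 3 to 6 without each library; 1 list stayed lower without haemoglobin, mitochondrial and rRNA genes, where 1 of 5 erythroid members was left (Alas2, −2.95). The estimated correlation between members was over 0.9 in 9 lists, among them pan-B and MHC class II (0.999 each), against the preset 0.01. The inflammatory and interferon response lists had estimated correlations of 0.026 and −0.038, yet lost their calls too (camera adjusted p = 0.588 each). Correlation between members therefore does not alone account for the lost calls. A call lost in this setting may reflect low power with 4 libraries. Fry called the plasma cell, interferon response and inflammatory lists only. The T cell, mature follicular and fibroblast lists lost the call with library totals (adjusted p = 0.144, 0.103 and 0.146) and with DESeq2 (0.366, 0.160 and 0.114), and the T cell list with limma-voom (0.0505). With DESeq2, 2383 calls were in the authors' deposited table and 71 in its short lists, against 632 and 42. Library correlations kept within 0.05.

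Directions turned with library totals for Lipe (0.50) and Mapk14 (0.31). The test direction of the endothelium list turned without a filter (median −0.43), with the replicate block (0.31), without immunoglobulin and T cell receptor genes (−0.45), and without WT replicate 2 (2.05) or KO replicate 2 (−0.21), and that of the p38 list with fry (−0.12) and without KO replicate 1 (−0.084). Without each library in turn, values ranged from −0.56 to 0.14 for Lipe, −0.10 to 4.98 for Zap70, −0.39 to 7.13 for Cd5, −0.60 to 2.57 for Bcl2 and −6.60 to 9.58 for Glycam1. List medians ranged from −0.55 to 5.73 for T cells, −0.014 to 3.43 for dendritic cells, −0.93 to 1.98 for precursor B cells, −0.61 to 2.05 for endothelium and −0.26 to −0.084 for p38. Of 1475 other values of 114 named genes, 1105 kept direction and side of the threshold, 151 lost the call, 212 gained it and 7 turned. The immunoglobulin constant list has no value without immunoglobulin genes. Leaving out a WT or KO library leaves that group with 1 sample, assumed to vary like the other group, so the small spread of the KO pair sets the counts without a WT library. In the simulation at the spread of all 4 libraries, which gave both groups the same spread, no 2-fold change was recovered.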

Other observations

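All tests in this part were chosen after the values were seen. Immunoglobulin V gene reads in KO were spread over many genes. Heavy chain V genes held 99371 and 114696 reads in KO and 237 and 4764 in WT, and 103 of 104 genes had reads in each KO library. The leading heavy chain V gene, AC073565.5, held 4.75% (exact 95% interval 4.62 to 4.88) and 5.04% (4.92 to 5.17) of these reads in KO. The effective number of heavy chain V genes (inverse Simpson index) was 51.3 and 50.6 in KO and 23.5 and 39.5 in WT, and of kappa V genes 51.0 and 51.8 in KO and 28.6 and 34.6 in WT. The V read depth differed far between these libraries, so no difference in this index is read from them. A hypothesis that a single clone supplied most immunoglobulin reads would need over 50% for 1 heavy chain V gene, and the largest share was 5.04%. This bears on reads, not cells: a clone with few immunoglobulin transcripts stays possible beside other plasma cells, and reads may be split between similar V genes.

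Epithelial genes were lower in KO. Going from TMM to library totals moved the median of all genes from 0.01 to 0.60 and the p38 list median from −0.12 to 0.46. Over 3 scalings the epithelial list median nearest 0 was −7.81 (log2 fold change, library totals, 95% bootstrap interval over members −8.25 to −6.03). Scaling moves genes about alike, so a list this far from 0 could not have turned, and this was no test of a cause. The values show only that the choice among these 3 scalings moved the list little beside its fall. Gland tissue in the WT samples is a candidate explanation: T cell list reads in WT replicate 1, the library with most Spt1, were 1.41% of those in WT replicate 2, so that library may hold gland rather than node. This ratio bears on WT replicate 1 only. Against WT replicate 2 the epithelial list median was −7.71, and that library also held gland transcripts, led by Dcpp2 at 5.76% of its reads. The epithelial list was written beforehand, and its abundant member Krt18 stood at 663 and 249 CPM in WT. An effect of genotype or tumour on gland cells stays open as untested.

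Inflammatory genes were higher in KO. Dilution of node RNA by gland RNA in WT would lower node genes alike, but against WT replicate 2 the inflammatory list median exceeded the pan-B median by 2.30 (log2; 95% bootstrap interval over members 1.24 to 3.52, 10000 resamples). That interval covers spread between genes, not between animals. The sex of the mice cannot be told apart from genotype for this list, since both WT libraries had Xist and both KO libraries Y-linked reads; 4 Y-linked genes were among the calls. More myeloid cells, more expression per cell, and tumour or genotype may each contribute, and stay open.

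Gland genes were present in KO replicate 2 at a low level. For 12 genes with at least 20000 reads in WT replicate 1 and a level over 5 times that in every other library (an rRNA gene was left out after its value was seen), the excess over KO replicate 1 was 0.527% to 1.77% (median 0.937%) of the WT replicate 1 count. WT replicate 2 as the source of the Xist reads is argued against: it would need 0.567% of its Xist count (95% counting interval 0.370 to 0.821), while 9 genes chosen in the same way for WT replicate 2 reached at most 0.206%. Of the WT replicate 1 count the Xist excess was 1.44%, inside the range of its gland genes, so material or reads from WT replicate 1 are a candidate source. No counting interval was put on this percentage, so WT replicate 1 was judged by a looser rule than WT replicate 2. Gland of the KO mouse itself stays open, since the excess of Xist over KO replicate 1 (exact conditional two-sided p = 3.0e-06) compares 2 libraries and covers counting error only.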
